A study of Mus musculus with 8 samples.

How the data were processed

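The data are droplet-based single-cell RNA-seq libraries from whole mouse brains. The mice carried p16-3MR, a transgene that reports activity of the promoter of Cdkn2a, the gene of the cell cycle inhibitor p16. Per the labels, 3 libraries came from mice given vehicle (DMSO and saline) and 5 from mice given paclitaxel, a taxane that stabilises microtubules, at 5 mg/kg/day by intraperitoneal injection in 2 cycles of 5 days, 7 days apart. Brains were collected up to 6 months after the treatment, and the labels give an age of 9 to 10 months. Per the labels' protocols, perfused brains were minced and digested with collagenase, hyaluronidase and elastase. The digest was passed through a 100 μm strainer, and vascular and perivascular cells were enriched on an iodixanol density gradient, so every share of cells below is a share of that fraction. All 8 libraries carry the same batch label. The labels name each library as a numbered sample of its group, and nothing else in them says that each came from a separate mouse. If some did not, the p-values measure only the spread between libraries, which may be technical.

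The deposited matrices hold raw UMI counts per gene and barcode for 32285 genes. Per the submitters' processing notes the authors used Cell Ranger 6.0.0 with the mm10 genome, and the file headers name the same Cell Ranger version; the gene annotation is not given in the sources used here. Symbols and Ensembl gene identifiers were taken from the files. Genes that share a symbol were kept apart by identifier. Coordinates were taken from GENCODE M21 on GRCm38, the assembly behind mm10, by Ensembl identifier. The files hold 27524 barcodes, the lowest with 500 UMIs.

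Cells with at most 15% mitochondrial UMIs and at least 500 detected genes were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked between 0.106% and 0.917% of a library's barcodes, so the expected share (0.8% for each 1000 barcodes) with the highest scores was removed instead. This left 19785 cells, between 1504 and 3163 per library. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes within libraries were reduced to 30 principal components, and cells were clustered with Leiden (leidenalg 0.10.2, resolution 1.0, 15 neighbours). The 37 clusters were named from marker lists fixed before the data were examined. A cluster got a name if at least 3 markers were each detected in 20% of its cells and the mean marker z score over clusters was at least 0.75. A cluster stayed unnamed if its 10 leading genes held more markers of another class or if markers of another class reached 0.6 of its own score. Endothelial cells were clustered again, on 20 components, and their 13 clusters were named as capillary, arterial or venous. This needed a zone score of at least 0.3 and a lead of 0.2 over the next zone. The fixed parts were the markers. The score thresholds, and leaving stress, interferon and other classes' genes out of the endothelial clustering, were set after seeing the clusters but before any comparison of the groups. These rules kept 5.18% of vehicle cells and 5.45% of paclitaxel cells out of every class, and a further 12.6% and 12.2% were endothelial-like cells without a zone. Stress or immune genes led some named clusters. Hspa1a and Fos led 1 endothelial cluster, Ifit1 and Isg15 another, Il1a, Atf3 and Egr1 a microglial one, and Lpl, Cst7 and Spp1 another microglial one. No annotation by the authors was used, and the names are rebuilt here, so differences from the study's own classes may come from the naming.

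Raw counts were summed per library and class. A class was tested if each of the 8 libraries held at least 20 of its cells, which left 9 separate classes and the endothelial cells of all zones together. Each was fitted with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood F test, group as the only term), with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. CPM values are edgeR's, with the TMM-scaled library size over the genes that passed the filter as the denominator. The genes named in the text follow a rule fixed at the same time. Genes past the threshold, with a mean of at least 20 CPM and no overlap between the groups, would be named by fold change, and in a class with fewer than 5 such genes the 5 with the smallest unadjusted p are named. The rule adds 18 senescence, barrier and activation genes for the capillary class and up to 4 members with the smallest p for each described list. Fold changes compare paclitaxel with vehicle. By chance alone 3.57% of genes would have no overlap between the 3 vehicle and the 5 paclitaxel libraries. In capillary cells 4.53% of tested genes had none, 207 higher and 255 lower with paclitaxel. In the tested classes this share lay between 3.17% (arterial) and 5.06% (smooth muscle). A level higher or lower in 5 of 5 paclitaxel libraries therefore says little by itself.

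A total of 46 gene lists, fixed at the same time as the markers, were tested with limma 3.58.1 camera (preset correlation 0.01) where at least 5 members were measured, with adjustment over the lists of a class. Camera with an estimated correlation and fry stand beside it. Over the 10 fits, 69 of 411 list tests passed with the preset correlation. None passed with an estimated correlation (lowest adjusted p = 0.231) or with fry (lowest adjusted p = 0.116), so every list call in the report is lost under both. With fry's mixed test, which asks for change in either direction, 8 passed.

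The senescence score of a cell was scanpy's score_genes over the union of 3 fixed lists (52 genes: senescence core, senescence effector and short secretory), on counts thinned to 1000 UMIs per cell. Thinning left out 1.43% of vehicle and 2.31% of paclitaxel cells. A score was called high above the 95th percentile of all cells of the class. Shares, scores and depths were compared between libraries with exact two-sided permutation tests over all 56 splits into 3 and 5. The smallest p these can give is 0.0179. After adjustment over classes or zones, a single fully separated class or zone could therefore not pass.

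The fits were tested on simulated counts drawn from each class's means, library sizes and dispersions, with 200 genes changed. For the capillary class (10068 genes run) 37.3% of genes changed 1.5-fold, 80.6% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, with 13 false calls. For fibroblast-like cells (6591 genes run), the class with the fewest cells, 43.3% of the 2-fold changes were recovered, and for microglia-like cells (10667 genes run) 85.1%. With 200 changed genes the adjustment is looser than where few genes change, and the simulated libraries share no structure beyond the groups. Fewer changes than these shares may therefore be found in the real data. Total UMIs per library lay between 14796745 and 26280964.

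Alternatives covered DESeq2 1.42.0, limma voom, upper-quartile factors, no factors, no filter on low counts, a block on the replicate number, equal cell numbers, each library left out in turn, other cell filters, doublet shares, resolutions, score lists, percentiles and depths, and list tests without genes that free RNA could bring. Those are genes whose share of UMIs in a class is within 3 times of their share over the other classes, and they were 8747 of the 10195 genes tested in capillary cells. Genes with a share more than 3 times higher in the other classes were kept, although free RNA could bring them too. A list that passes without the removed genes is therefore not shown to be free of such RNA. The replicate block used only the replicate numbers present in both groups, so it left out paclitaxel 4 and 5. A turn of direction under an alternative was counted where the value as reported had an unadjusted p under 0.32 or where either value passed the threshold; other changes of sign were not counted.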

Results

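Single-cell transcriptomes were collected from the cerebrovascular fraction of brains of p16-3MR mice, 3 vehicle libraries and 5 paclitaxel libraries, to look for senescent cells in the brain after chemotherapy. Total UMIs per library ranged from 14796745 to 26280964. After filtering, 2585, 2022 and 2402 cells remained in the vehicle libraries and 3163, 2733, 1504, 2648 and 2728 in the paclitaxel libraries. The median UMI count per kept cell was 5951 ± 406 (SD, n = 3) in vehicle and 5781 ± 546 (n = 5) in paclitaxel libraries (exact two-sided permutation p = 0.643), and the median number of detected genes was 2406 ± 102 and 2354 ± 140 (exact p = 0.589). Filters and doublet removal took out 28.5% ± 0.835 and 28.2% ± 4.87 of the barcodes (exact p = 0.929). Xist, the RNA that coats the inactive X chromosome, had a UMI in between 85.5% and 88.6% of the kept cells of every library, whereas the Y-linked genes Ddx3y and Eif2s3y had 0 UMIs in every library. The labels give the mice as male, and the libraries of both groups had this same pattern.

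Endothelial-like cells were the most frequent class, with 8162 cells, and microglia-like cells (4390) and pericyte-like cells (2115) followed. Endothelial-like cells of all zones made up 42.3% ± 5.43 (SD, n = 3) of kept cells in vehicle and 39.9% ± 8.78 (n = 5) in paclitaxel libraries, and microglia-like cells 20.4% ± 5.45 and 23.6% ± 6.44. Capillary endothelial-like cells, recognised by transporters and other genes of the exchange vessels such as Mfsd2a and Slc16a1, numbered 3776 and made up 19.3% ± 3.73 and 18.6% ± 3.78. Pericyte-like cells made up 10.6% ± 1.38 and 10.8% ± 1.72, oligodendrocyte-like cells 6.46% ± 3.52 and 5.73% ± 2.03, and venous endothelial-like cells 7.12% ± 1.71 and 5.89% ± 1.33. Arterial endothelial-like cells (652), astrocyte-like cells (657), smooth muscle-like cells (762) and fibroblast-like cells (274) each made up less than those. The differences in these shares lay within the spread between libraries (adjusted p = 1.0 in each exact permutation test; unadjusted exact p = 0.304 for the venous class). Among endothelial-like cells, the capillary zone held 45.4% ± 5.25 in vehicle and 46.7% ± 1.40 in paclitaxel libraries (exact p = 0.661), the venous zone 17.2% and 14.9%, and the arterial zone 7.73% and 7.86%.

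**Figure D1:**
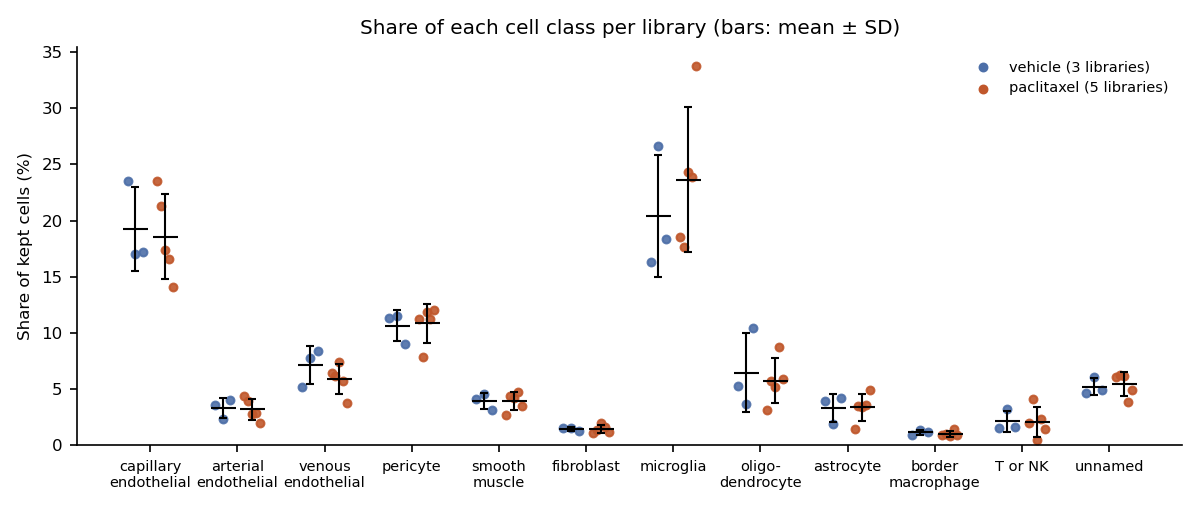
Share of kept cells (%, vertical axis) in each named cell class (horizontal axis) per library, with vehicle and paclitaxel libraries in separate colours and bars at the group means with SD. Capillary endothelial-like cells average 19.3% in vehicle and 18.6% in paclitaxel libraries, and the points of both groups overlap in every class.

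Senescence was measured in capillary endothelial-like cells first, a cell type that the series' design text names. None of the measures in those cells passed its test. The share of capillary cells with a high senescence score was 6.49% ± 3.47 (SD, n = 3) in vehicle and 4.25% ± 1.39 (n = 5) in paclitaxel libraries (exact permutation p = 0.268, adjusted p = 0.607), a difference that turned to 0.379 percentage points higher in paclitaxel with the long secretory list. Paclitaxel minus vehicle was −2.24 percentage points, −0.354 without vehicle 2 and −3.76 without vehicle 3. The mean score was 0.163 ± 0.0199 and 0.156 ± 0.00412 (exact p = 0.5, adjusted p = 0.714), with a difference of 0.00288 in the other direction without vehicle 2. Cdkn1a, which encodes the cell cycle inhibitor p21, had 733 ± 439 CPM in vehicle and 521 ± 189 CPM in paclitaxel capillary cells (log2 fold change −0.49 ± 0.47 SE; edgeR quasi-likelihood adjusted p = 0.88, lower than every vehicle library in 1 of 5 paclitaxel libraries). At equal depth, 43.8% ± 19.8 and 36.6% ± 7.90 of capillary cells had a Cdkn1a UMI (exact p = 0.536; without vehicle 2 the paclitaxel mean was 3.86 percentage points higher), and without thinning 78.7% ± 12.3 and 71.1% ± 8.40 (exact p = 0.304). At equal depth over all libraries the share was 38.4% in capillary, 26.9% in arterial endothelial-like, 17.5% in venous endothelial-like and 11.2% in smooth muscle-like cells. In pericyte-like cells, with a median of 4342 UMIs against 4732 in capillary cells, it was 1.20%. In T- or NK-like cells, with a median of 6975, it was 0.714%. Cdkn2a, the gene behind the p16 reporter, was seen in few cells. It had a UMI in 12 of 3776 capillary cells without thinning (0.354% ± 0.422 in vehicle and 0.213% ± 0.146 in paclitaxel libraries, exact p = 0.589), and in 1 of 3651 at equal depth (0.0274%, Wilson 95% interval 0.00484 to 0.155%). Without thinning the share over all libraries was 0.318% in capillary cells, 0.0946% in pericyte-like cells, 0.0813% in venous endothelial-like cells (median 7635 UMIs), 2.28% in microglia-like cells and 5.92% in T- or NK-like cells, and 0 of 762 smooth muscle-like cells (median 12960 UMIs) had one. The highest share was 7.41%, in 81 B-like cells. In fibroblast-like cells it was 3.65% (6.94% ± 0.663 in vehicle and 1.80% ± 2.90 in paclitaxel libraries, exact permutation p = 0.0714). Without the filter on low counts Cdkn2a and Cdkn1a were among 22 genes called in fibroblast-like cells. Cdkn1a there had 87.2, 59.4 and 20.9 CPM in vehicle and 0, 22.8, 39.8, 9.35 and 3.94 CPM in paclitaxel libraries. Without paclitaxel 3 Cdkn1a was called in smooth muscle-like cells. In the fit of all libraries with the filter, neither class had a called gene. At equal depth the 1 capillary cell was in a paclitaxel library. With 12 such cells the data say little about a difference between groups in Cdkn2a.

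**Figure D2:**
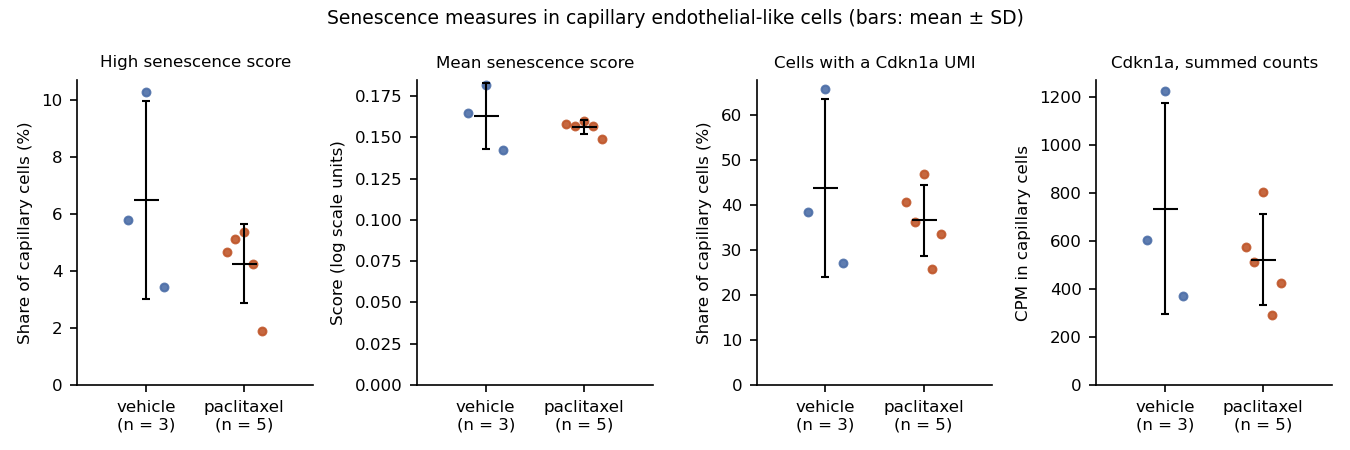
Senescence measures in capillary endothelial-like cells, 1 point per library with the group mean and SD: share of cells with a high senescence score (%), mean senescence score, share of cells with a Cdkn1a UMI at equal depth (%) and Cdkn1a level (CPM). High-score shares average 6.49% in the 3 vehicle and 4.25% in the 5 paclitaxel libraries, with the wider spread among the vehicle libraries.

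Other senescence and stress genes in capillary cells gave no call. Trp53, the p53 gene, stood at 54.8 ± 8.31 and 50.1 ± 10.7 CPM, Cdkn2b (p15) at 70.1 ± 3.49 and 74.1 ± 11.5 CPM, and Lmnb1, a nuclear lamina gene, had a log2 fold change of −0.15 ± 0.22 SE. Of the senescence core list 7 members were measured and 2 had a positive fold change (camera adjusted p = 0.369). The effector list (adjusted p = 0.656), the short (0.617) and long (0.964) secretory lists, p53 targets (0.475), DNA damage response (0.656) and interferon response (0.901) did not pass either. Adjusted over the list alone, 0 genes passed in these lists except Gadd45a, a stress-induced growth arrest gene among the p53 targets, at 12.2 ± 3.72 and 21.9 ± 3.65 CPM (log2 fold change 0.79 ± 0.21 SE, higher than all vehicle libraries in 5 of 5). Gdf15, Plvap and Cdkn2a had too few counts for the fit, with 3, 22 and 12 UMIs in all capillary cells. In the other classes, oligodendrocyte-like cells had 6.52% high-score cells in vehicle and 4.13% in paclitaxel libraries (exact p = 0.0357, adjusted p = 0.268) and astrocyte-like cells 6.54% and 4.43% (exact p = 0.0536). These differences turned direction, to 0.288 percentage points higher in paclitaxel oligodendrocyte-like cells with counts thinned to 2000 UMIs and to 3.46 higher in astrocyte-like cells with the core list alone. The difference in effect between classes was tested in 16 comparisons and none passed (lowest adjusted p = 0.881). Senescence core genes as a list fell in venous endothelial-like cells, with 0 of 7 members positive (camera adjusted p = 0.0418), and in the endothelial cells of all zones, with 1 of 7 positive (adjusted p = 0.0313). These calls are lost with adjusted p = 0.948 and adjusted p = 0.973 with an estimated correlation. The venous call is also lost without vehicle 2 (adjusted p = 0.275), paclitaxel 2 (0.132) or paclitaxel 5 (0.0733). The all-zone call is lost without vehicle 1 (0.154), vehicle 2 (0.152), paclitaxel 2 (0.0657) or paclitaxel 5 (0.0919).

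In capillary endothelial-like cells Smad7, an inhibitor of TGF-beta and BMP signalling, rose from 217 ± 33.0 CPM (SD, n = 3) in vehicle to 372 ± 38.5 CPM (n = 5) in paclitaxel libraries. Its log2 fold change was 0.78 ± 0.11 SE (adjusted p = 0.00606), and all 5 paclitaxel libraries lay above all 3 vehicle libraries. It was the 1 gene of 10195 past the threshold of edgeR's quasi-likelihood test, with 666 genes at an unadjusted p under 0.05. Smad7 (gene identifier ENSMUSG00000025880) lies on chromosome 18, 75367529 to 75395935, on the plus strand (GRCm38). Without the vehicle 3 library the log2 fold change was 0.66 and the call was lost (adjusted p = 0.141). The other 4 genes with the smallest p did not pass. They are Id2, a BMP-responsive inhibitor of differentiation (72.5 ± 9.54 and 115 ± 18.1 CPM, log2 fold change 0.66 ± 0.13 SE, adjusted p = 0.216, higher in 5 of 5), Adamtsl2 (25.4 and 13.1 CPM), Ccdc152 (93.6 and 62.7 CPM) and Phpt1 (log2 fold change −0.85 ± 0.18 SE). As a list, genes of the TGF-beta and BMP response rose, with 18 of 19 measured members positive and a median log2 fold change of 0.19 (camera adjusted p = 8.7e-06); 2 genes were higher adjusted over the list alone, Smad7 and Id2. The call is lost, with adjusted p = 0.662 with an estimated correlation and 0.0733 without the 8747 genes that free RNA could bring. Id3 stood at 1360 ± 122 and 1592 ± 117 CPM and Eng, an endothelial co-receptor for TGF-beta ligands, had a log2 fold change of 0.22 ± 0.10 SE.

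**Figure D3:**
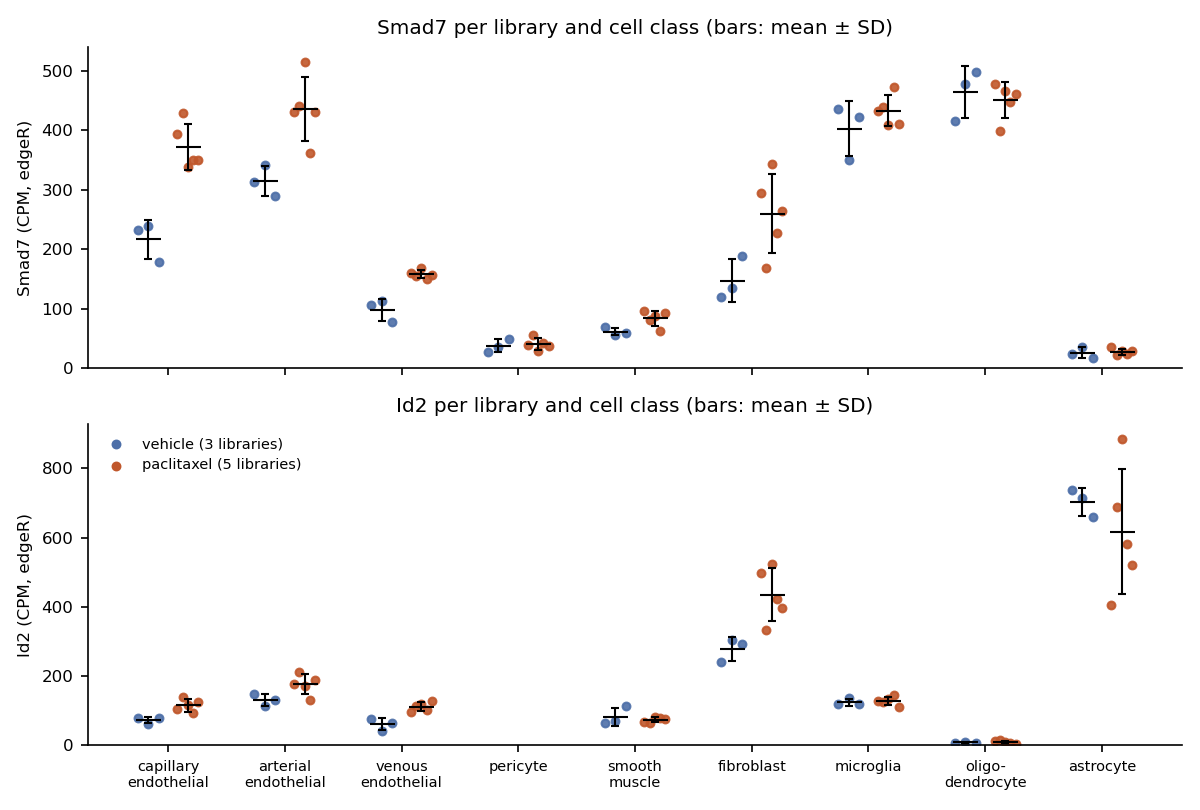
Smad7 (upper plot) and Id2 (lower plot) levels (CPM, vertical axis) per library in the 9 separate cell classes (horizontal axis), 1 point per library in its group's colour, with bars for the group mean and SD; Id2 had too few counts to test in pericyte-like cells and is not plotted there. In capillary cells Smad7 averages 217 CPM in the 3 vehicle and 372 CPM in the 5 paclitaxel libraries, without overlap.

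Barrier and activation genes of capillary cells showed no call in the fit of all libraries with the filter on low counts. Under alternatives 2 of those named here passed. Vcam1 passed without the paclitaxel 2 library. Vwf passed with the replicate block, which left out paclitaxel 4 and 5, and without the filter on low counts. The tight junction genes Cldn5 (5926 ± 817 and 6827 ± 320 CPM) and Ocln (337 ± 16.1 and 362 ± 38.4 CPM) had log2 fold changes of 0.20 and 0.10, and the transporters Slc2a1 (2295 and 2152 CPM), Mfsd2a (352 and 325 CPM) and Abcb1a (1381 and 1305 CPM) of −0.09, −0.12 and −0.08. The adhesion molecules Vcam1 (31.0 ± 8.91 and 62.3 ± 22.7 CPM) and Icam1 had log2 fold changes of 0.94 ± 0.45 and 0.57 ± 0.44 SE. Vwf, the von Willebrand factor gene, stood at 123 ± 7.68 and 179 ± 40.2 CPM (0.55 ± 0.16 SE, adjusted p = 0.65, higher in 5 of 5), Nos3 at 158 and 169 CPM and Kdr at 682 and 679 CPM. Lists of tight and adherens junctions (adjusted p = 0.405), barrier transport (0.146) and endothelial activation (0.462) did not pass. With 1 library left out the camera adjusted p of endothelial activation ranged from 0.0345 to 0.918. Vasoregulation genes rose as a list, with 11 of 14 positive (camera adjusted p = 0.0353), led by Edn1, the endothelin-1 gene, at 127 ± 40.7 and 245 ± 44.3 CPM. That call has adjusted p = 0.662 with an estimated correlation and 0.125 without genes that free RNA could bring, and it was lost without vehicle 3 (0.275), paclitaxel 1 (0.132), paclitaxel 2 (0.0592) or paclitaxel 3 (0.0659).

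Genes of nuclear-encoded oxidative phosphorylation fell in capillary cells, with 10 of 89 positive and a median log2 fold change of −0.15 (camera adjusted p = 1.2e-10). Cox6c, for example, had 660 ± 22.1 CPM in vehicle and 534 ± 34.6 CPM in paclitaxel libraries. Ribosomal protein genes fell too, with 7 of 88 positive and a median of −0.12 (adjusted p = 2.7e-07), and 6 were lower adjusted over the list alone, among them Rps26 at 882 ± 81.0 and 718 ± 29.5 CPM. Both calls are lost at adjusted p = 0.743 with an estimated correlation. Cholesterol synthesis genes (3 of 20 positive, adjusted p = 0.00909) and glucocorticoid response genes (7 of 19 positive, adjusted p = 0.0147) fell, each with adjusted p = 0.743 with an estimated correlation. Examples are Msmo1 at 50.2 and 36.8 CPM and Nfkbia, the NF-kB inhibitor gene, at 1373 ± 393 and 938 ± 185 CPM. Immediate early genes, which respond within minutes to stimulation and to tissue handling, rose with 24 of 28 positive (adjusted p = 5.6e-04, and adjusted p = 0.744 with an estimated correlation). Disease-associated microglia genes rose with 12 of 15 positive and 3 higher adjusted over the list alone (adjusted p = 1.8e-04, and adjusted p = 0.662 with an estimated correlation). Apoe, a member of that list, stood at 821 ± 70.0 and 1058 ± 142 CPM. Microglial marker genes, which capillary cells should lack, rose alongside with 8 of 8 positive (adjusted p = 0.0232, and adjusted p = 0.743 with an estimated correlation). Without the 8747 genes that free RNA could bring, the calls were lost for immediate early (adjusted p = 0.658) and glucocorticoid response genes (0.0765). Disease-associated microglia genes still passed the threshold. That does not argue against free RNA for them, since genes with a far higher share in other classes stayed in the test. The oxidative phosphorylation, ribosomal and cholesterol lists then had too few members left to test. Glucocorticoid response genes turned direction without vehicle 2 (adjusted p = 0.871) and lost their call without paclitaxel 2 (0.0592) or 4 (0.226). Immediate early genes lost theirs without vehicle 1 (0.471) or paclitaxel 5 (0.494). The cholesterol call was lost without vehicle 1 (0.441), vehicle 2 (0.0763), paclitaxel 1 (0.15) or paclitaxel 4 (0.091). That of microglial markers was lost without vehicle 1 (0.293), vehicle 3 (0.275), paclitaxel 1 (0.123) or paclitaxel 5 (0.328).

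In venous endothelial-like cells Ch25h, the cholesterol 25-hydroxylase gene, fell from 306 ± 26.0 to 155 ± 34.7 CPM (log2 fold change −0.99 ± 0.15 SE, adjusted p = 0.0250, lower in 5 of 5). In arterial endothelial-like cells Tuba1b, an alpha-tubulin gene, fell from 244 ± 32.0 to 142 ± 21.1 CPM (−0.77 ± 0.14 SE, adjusted p = 0.0173, lower in 5 of 5). Each was the 1 call of its class, of 9614 genes with 690 at an unadjusted p under 0.05 in venous and of 8324 with 378 in arterial cells. Tuba1b has near-identical paralogs, so its counts are uncertain. Venous cells also had Tfrc, the transferrin receptor gene, at 89.2 ± 16.8 and 164 ± 27.3 CPM (adjusted p = 0.0590), Atf3 at 39.3 and 74.3 CPM, Smad7 at 98.2 ± 18.8 and 158 ± 6.83 CPM (0.69 ± 0.13 SE, adjusted p = 0.0590) and Id2 at 60.4 ± 17.7 and 111 ± 13.1 CPM, which did not pass. Arterial cells had Smad7 at 315 ± 25.6 and 436 ± 54.3 CPM, Nfkbia at 962 and 661 CPM, Hspb1 at 935 and 1309 CPM and Nmt1 at 121 and 79.4 CPM, none of them past the threshold. Glucocorticoid response genes fell in venous cells, with 3 of 19 positive and 3 lower adjusted over the list alone (camera adjusted p = 1.3e-08), Wnt and barrier transcription genes rose with 18 of 24 positive (0.00133), and TGF-beta and BMP response genes rose with 13 of 19 positive (0.00683). Each of these has adjusted p = 0.948 with an estimated correlation. TGF-beta and BMP response genes rose in arterial cells with 15 of 19 positive (adjusted p = 0.00851, and adjusted p = 0.719 with an estimated correlation), and mural marker genes there fell with 0 of 7 positive (adjusted p = 6.7e-09, and adjusted p = 0.643 with an estimated correlation). The TGF-beta and BMP call is lost without vehicle 3 or paclitaxel 5 in arterial (adjusted p = 0.241 and 0.142) and venous cells (0.0923 and 0.178), and the venous glucocorticoid call without vehicle 2 (0.054). With all zones together 0 of 12086 genes passed in edgeR, with 822 at an unadjusted p under 0.05; DESeq2 called 5 and voom 1. The smallest p there belonged to Smad7 (log2 fold change 0.62 ± 0.09 SE, adjusted p = 0.0719), Usp53 (251 and 357 CPM), Otud7b (49.3 and 63.9 CPM), Id2 (74.8 and 122 CPM) and Phpt1 (24.0 and 16.1 CPM). Ch25h lost its call without vehicle 2 (adjusted p = 0.108), vehicle 3 (0.301), paclitaxel 2 (0.147), paclitaxel 3 (0.0602) or paclitaxel 5 (0.147), or with equal cell numbers (0.0572). Tuba1b lost it without vehicle 2 (0.137), vehicle 3 (0.221) or paclitaxel 1 (0.0934), with equal cell numbers (0.432), 10% mitochondrial UMIs (0.0523), 1000 genes (0.0589), no doublet removal (0.131), 3 times the doublet share (0.125) or resolution 2.0 (0.695).

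In pericyte-like cells Nts, the neurotensin gene, fell from 111 ± 27.6 to 55.7 ± 11.5 CPM (log2 fold change −0.98 ± 0.16 SE, adjusted p = 0.00992, lower in 5 of 5), and Gm13536 from 53.5 ± 13.4 to 26.7 ± 5.66 CPM (adjusted p = 0.0303, SE of the log2 fold change 0.19). Gm13536 is annotated as antisense, so its reads cannot be told apart from those of its partner unless counting used the strand. These were the 2 calls among 9743 genes, with 624 at an unadjusted p under 0.05. Rgs4 stood at 1767 ± 313 and 1348 ± 46.0 CPM, Apoe at 246 ± 37.6 and 378 ± 68.2 CPM and Nmt1 at 113 and 72.5 CPM, which did not pass. In smooth muscle-like cells 0 of 9155 genes passed in edgeR, with 627 at an unadjusted p under 0.05, and DESeq2 called 1. The smallest p there belonged to Ahnak (424 ± 33.5 and 577 ± 63.5 CPM), Rps26 (634 and 487 CPM), Plin4 (84.2 and 123 CPM), Apoe (151 and 201 CPM) and Igfbp7 (4428 and 3621 CPM). Their immediate early genes rose with 24 of 26 positive (camera adjusted p = 2.7e-12, and adjusted p = 0.393 with an estimated correlation), with Atf3 at a log2 fold change of 2.29 ± 0.75 SE. In fibroblast-like cells 0 of 6903 genes passed, with 383 at an unadjusted p under 0.05. The smallest p there belonged to Cavin2 (0 CPM in each vehicle library and 21.9 ± 10.2 CPM in paclitaxel libraries), Mturn (3.45 and 26.3 CPM), Dele1 (22.8 and 58.6 CPM), Hmgn2 (170 and 94.0 CPM) and Dhps (16.2 and 43.4 CPM). Cholesterol synthesis genes fell there with 1 of 17 positive (adjusted p = 1.1e-05, and adjusted p = 0.547 with an estimated correlation). Nts lost its call without vehicle 1 (log2 fold change −0.74, adjusted p = 0.0691) or paclitaxel 3 (0.131). Gm13536 lost its call in DESeq2 (adjusted p = 0.167) and without vehicle 1 (0.0691), vehicle 2 (0.987), paclitaxel 1 (0.380), paclitaxel 2 (0.0668) or paclitaxel 3 (0.131).

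In oligodendrocyte-like cells the chaperone gene Hsp90aa1 rose from 1612 ± 236 to 2270 ± 136 CPM (log2 fold change 0.50 ± 0.09 SE, adjusted p = 0.0233), and Hspa4l, another heat shock gene, from 70.7 ± 13.7 to 107 ± 9.00 CPM (0.66 ± 0.13 SE, adjusted p = 0.0419). Txnrd1, a thioredoxin reductase of the oxidative stress response, rose from 23.6 ± 10.6 to 48.1 ± 6.41 CPM (1.25 ± 0.22 SE, adjusted p = 0.0419). These 3 of 9364 genes passed, each higher in 5 of 5 paclitaxel libraries, with 488 at an unadjusted p under 0.05. Wfdc18 (43.7 ± 11.3 and 23.8 ± 5.84 CPM, adjusted p = 0.0502) and Arrdc3 (328 and 244 CPM) did not pass. Heat shock and protein folding genes rose as a list with 16 of 27 positive (camera adjusted p = 2.7e-04), and 5 were higher adjusted over the list alone, Hsp90ab1 (1881 ± 331 and 2620 ± 229 CPM) and Cryab (3094 ± 504 and 4134 ± 339 CPM) among them. Oxidative stress response genes rose with 18 of 21 positive (adjusted p = 1.4e-04). Both have adjusted p = 0.992 with an estimated correlation. In astrocyte-like cells Hspa5, a chaperone of the endoplasmic reticulum, rose from 221 ± 37.5 to 380 ± 45.2 CPM (0.74 ± 0.14 SE, adjusted p = 0.0212, higher in 5 of 5), the 1 call of 8164 genes with 533 at an unadjusted p under 0.05. Neat1, a nuclear long noncoding RNA (421 ± 30.3 and 658 ± 158 CPM), Dbi (log2 fold change −0.54 ± 0.12 SE), Tomm7 (141 and 80.9 CPM) and Gm17167 (26.6 and 62.3 CPM) did not pass. Their tubulin and microtubule genes fell with 8 of 22 positive (adjusted p = 0.00176, and adjusted p = 0.374 with an estimated correlation). In microglia-like cells 0 of 10823 genes passed in edgeR, DESeq2 or voom, with 502 at an unadjusted p under 0.05 in edgeR. The smallest p there belonged to Nes (10.9 and 20.3 CPM), Adamts1 (log2 fold change 0.58 ± 0.12 SE), Ccdc152 (112 and 79.9 CPM), Neat1 (249 and 339 CPM) and Dync1i2 (209 and 165 CPM). Oxidative stress response genes rose in microglia-like cells with 20 of 22 positive (adjusted p = 2.0e-05, and adjusted p = 0.532 with an estimated correlation), and endothelial marker genes rose there with 9 of 9 positive (adjusted p = 0.00340, and adjusted p = 0.694 with an estimated correlation). Without vehicle 3 the calls were lost for heat shock (adjusted p = 0.611) and oxidative stress genes (0.395) in oligodendrocyte-like and oxidative stress genes in microglia-like cells (0.294). The microglial endothelial markers lost theirs without vehicle 2 (0.115), paclitaxel 1 (0.0877) or paclitaxel 2 (0.22). In edgeR's test Hsp90aa1 lost its call without vehicle 3 (log2 fold change 0.38, adjusted p = 0.786), paclitaxel 1 (0.0702) or paclitaxel 2 (0.101), with equal cell numbers (0.12) or no doublet removal (0.0744). Hspa5 lost its call without vehicle 2 (0.344), vehicle 3 (0.370) or paclitaxel 2 (0.0979), with equal cell numbers (0.135), 10% mitochondrial UMIs (0.302) or no normalization factors (0.0725). Without vehicle 3 Hspa4l (adjusted p = 0.999) and Txnrd1 (log2 fold change 0.81, adjusted p = 0.808) lost theirs, as did both without vehicle 1 (0.0774), without paclitaxel 1 (0.108 and 0.167) or 2 (0.112), with equal cell numbers (0.405 and 0.340, Txnrd1 at a log2 fold change of 0.85) and with no doublet removal (0.0859 and 0.0744). Hspa4l also lost its call in DESeq2 (0.0608). Txnrd1 also lost its call without paclitaxel 4 (0.0652) or 5 (0.104) or with 10% mitochondrial UMIs (0.0638).

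Over the 9 separate classes, nuclear oxidative phosphorylation genes fell in 8 and had a median log2 fold change below 0 in 9. Ribosomal protein genes fell in 6, and glucocorticoid response genes in 5, with medians below 0 in 9 for each. TGF-beta and BMP response genes rose in 3, the capillary, arterial and venous classes. Microglial marker genes rose in 4 of the 8 classes where they were tested. None of the list calls passed with an estimated correlation (lowest adjusted p = 0.231). All classes come from the same 8 libraries, so a shift of whole libraries could move them together. The counts of classes are therefore not replication.

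**Figure D4:**
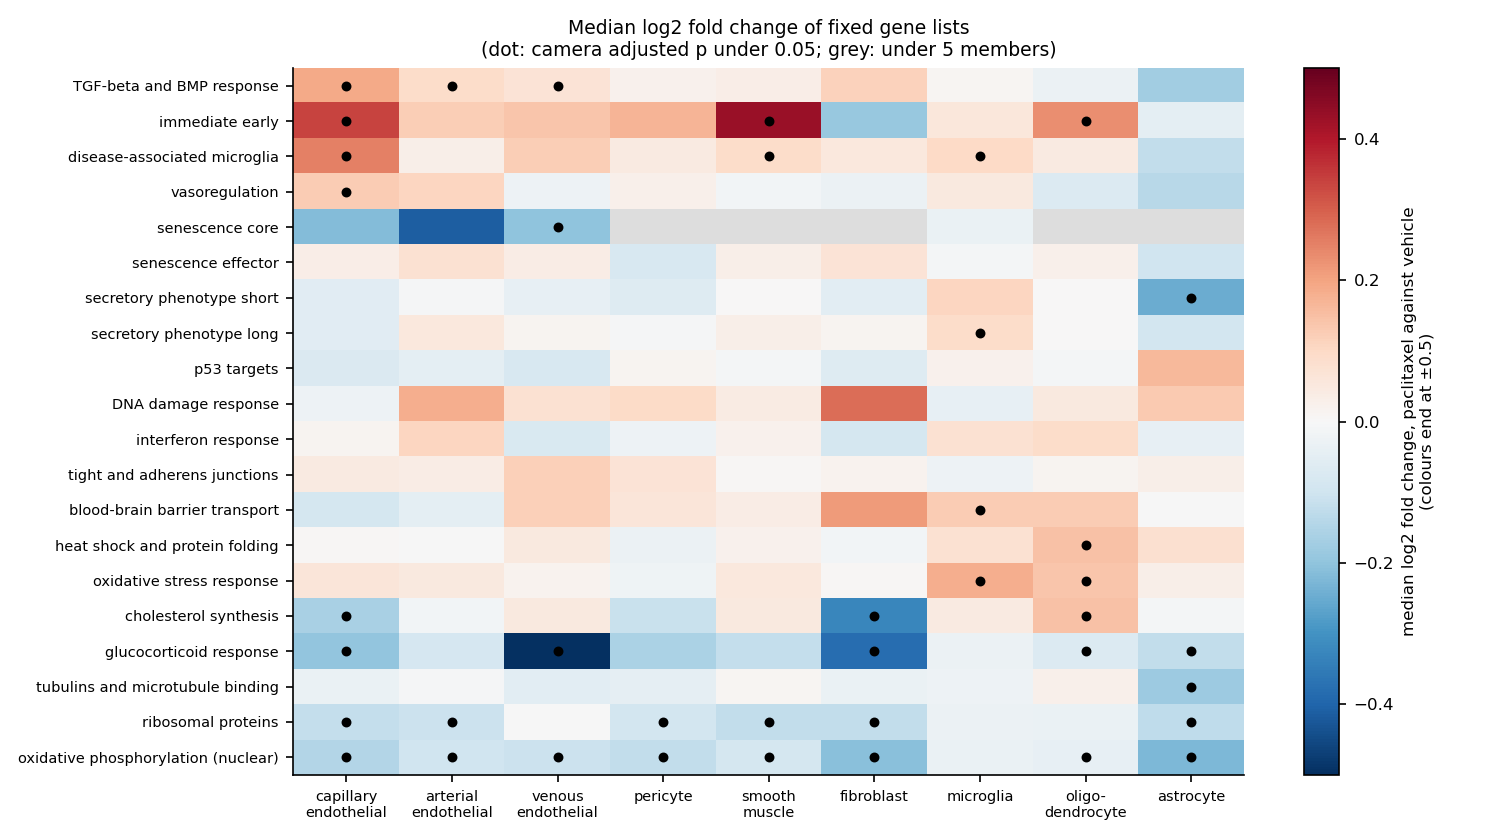
Median log2 fold change (paclitaxel against vehicle, colour) of gene lists (vertical axis) in the 9 separate cell classes (horizontal axis), with a mark where camera passed. Oxidative phosphorylation medians lie below 0 in 9 classes, which come from the same 8 libraries and are not independent.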

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

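The tests of RNA from other cells for Smad7, of transcript length and UMIs per cell, and of the heat shock genes were chosen after the results were seen.

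In capillary endothelial-like cells Smad7 rose by 156 CPM. RNA from other cells that enters all droplets alike is argued against by pericyte-like cells, where the gain was 2.54 CPM. Astrocyte-like cells gained 1.7 CPM, and oligodendrocyte-like cells changed by −13.2 CPM. But fibroblast-like cells gained 112 CPM (log2 fold change 0.82 ± 0.22 SE), microglia-like cells 30.1 CPM and smooth muscle-like cells 22.4 CPM, none past the threshold. Whether the rise was confined to endothelial-like cells therefore stays open. A shift between capillary clusters is argued against by the log2 ratio of 0.66 that remained with the clusters weighted equally. A response to paclitaxel may explain the rise, as a hypothesis from the same data. But other splits of the 8 libraries do not exclude chance, since the real split gave 1 gene in capillary cells and the highest other 45.

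Genes of oxidative phosphorylation and ribosomal proteins fell as lists in capillary cells, by medians of −0.15 and −0.12 on the log2 scale. For oxidative phosphorylation, genes matched on length and level fell less, with a median of −0.0352 ± 0.00973 (bootstrap SD over genes). That argues against transcript length as the whole cause in these libraries. For ribosomal proteins the matched median of −0.041 ± 0.0226 leaves it open. With 4 groups of capillary cells by UMI count weighted equally, median log2 ratios of −0.123 ± 0.0104 and −0.0915 ± 0.0151 remained of −0.141 and −0.117. These argue against different UMIs per cell as the whole cause in these libraries. The bootstraps draw genes, which may move together, and not libraries, so the SDs leave out the spread between libraries. Neither call holds with an estimated correlation between genes, so a shift of whole libraries that moves these genes together stays open. A response to paclitaxel was not tested apart from it.

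Hsp90aa1, Hspa4l and the heat shock list rose in oligodendrocyte-like cells. All of these calls are lost without vehicle 3, and that of the list also with an estimated correlation. RNA from the other tested classes is argued against for Hsp90aa1, whose highest mean in another tested class was 520 CPM (paclitaxel smooth muscle-like cells). It is argued against for Hspa4l too, whose rise would need 67.8% of pericyte RNA while 20 abundant pericyte genes gained a median of 0.0267% and at most 6.09%. Classes with too few cells to test, such as neuron-like cells, were not compared and stay open as a source. Handling stress that acts on all classes of a library alike is argued against as the whole cause for Hsp90aa1 by the other 8 classes. Their mean log2 effect was −0.0303, and 0 of the 8 were higher at an unadjusted p under 0.05. The effect in oligodendrocyte-like cells lay 0.539 above that mean (exact p = 0.0179, adjusted p = 0.0268 over 3 tests). Hsp90aa1 was picked for its rise in these same cells and libraries, so this p is no independent support, and 0.0179 is the smallest possible. Against single classes 0 of 51 exact tests of called genes passed (lowest adjusted p = 0.0506, and 0.187 for Hsp90aa1 against microglia-like cells). Tests at the smallest possible exact p of 0.0179 still reached only that adjusted p of 0.0506. The count of 0 therefore does not show that effects were alike between classes. Handling stress stays open for Hspa4l, 0.461 above its mean over the other classes but also with a log2 fold change of 0.49 ± 0.19 SE in capillary cells (unadjusted p = 0.0174). It stays open too for the list, 0.110 above its mean over the other classes (adjusted p = 0.321). The list passed upwards in 1 of 9 classes, while immediate early genes did in 3. A response to paclitaxel may explain the rise, as a hypothesis, and other splits do not exclude chance, since the real split gave 3 genes and the highest other 59.

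For the remaining classes with a called gene other splits do not exclude chance either. The real and the highest other counts were 1 and 5 in arterial, 1 and 56 in venous, 1 and 5 in astrocyte-like and 2 and 16 in pericyte-like cells. Of the 56 splits, as many genes as the real one came from 23 in arterial, 17 in astrocyte-like, 16 in capillary, 11 in venous, 10 in pericyte-like and 6 in oligodendrocyte-like cells. Where the real count was 0, all 56 splits give at least as many by definition, so their number decides nothing. The highest other counts there were 19 in endothelial cells of all zones, 25 in fibroblast-like, 8 in microglia-like and 33 in smooth muscle-like cells. The split of paclitaxel 1, 2 and 3 against the rest gave the highest count in capillary, all-zone endothelial, oligodendrocyte-like and pericyte-like cells. The all-zone cells include the capillary ones, and in each of the remaining fits a different split was highest. A structure of the samples apart from the groups is possible but was not tested.

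Some single paclitaxel libraries stood far from the other 4 of their group, 9 in 123 groups of values tested, where chance gives about 1 in 20. Paclitaxel 4 stood apart in capillary cells for Abcb1a (1032 CPM, nearest 1351) and Trp53 (68.6 CPM, nearest 48.7), and for Hspb1 in arterial cells (1608 CPM, nearest 1277). It also had the highest border macrophage share (1.40%, nearest 0.951%). The 1 capillary cell with a Cdkn2a UMI at equal depth (0.236%) is among the 9, but with 0 in the other 4 libraries any single cell would stand apart, so it says nothing about that library. Paclitaxel 2 stood apart for Vcam1 in capillary cells (23.2 CPM, nearest 67.5) and for the pericyte share (7.83%, nearest 11.2%). Paclitaxel 1 had Dync1i2 at 139 CPM in microglia-like cells (nearest 166), and paclitaxel 3 a mean arterial senescence score of 0.165 (nearest 0.138).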

How the results depend on the processing

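No alternative was added after the results were seen, and where a value changed the cause was not tested. Class and zone shares (289 values) stayed short of the threshold under every alternative run. So did depth with the shares of cells with a Cdkn1a or Cdkn2a UMI (216 values). For the shares this was nearly fixed by the smallest possible exact p and the adjustment, so it shows little about stability. Many values changed sign with 1 library left out. Paclitaxel minus vehicle in percentage points then ranged from −15.4 to 3.86 for the Cdkn1a share in capillary, −16.1 to 4.99 in arterial and −17.2 to 1.27 in all-zone cells. It ranged from −1.93 to 1.46 for the capillary and −2.12 to 1.25 for the oligodendrocyte share of cells, and from −1.58 to 3.56 for the capillary share of endothelial cells. Median UMIs ranged from −386 to 16.4. Counts of called genes did not hold their size. Without a filter on low counts they were 9 in arterial, 6 in astrocyte, 52 in capillary, 3 in all-zone endothelial, 22 in fibroblast, 16 in microglia, 21 in oligodendrocyte, 11 in pericyte, 33 in smooth muscle and 72 in venous cells. The replicate numbers do not pair the libraries (correlations between −0.132 and 0.115). The replicate block also left out paclitaxel 4 and 5, so its results mix a change of libraries with a change of model. The block gave 13 in arterial, 11 in astrocyte, 34 in capillary, 6 in all-zone and 2 in microglia cells. It gave 26 in oligodendrocyte, 17 in pericyte, 6 in smooth muscle and 3 in venous cells. DESeq2 gave 5 in capillary, 5 in all-zone, 1 in smooth muscle and 14 in venous cells, and voom 2 in astrocyte and 1 in all-zone cells. No normalization factors gave 0 in astrocytes. Equal cell numbers gave 0 in arterial, 2 in astrocyte, 3 in capillary, 1 in all-zone, 2 in microglia, 0 in oligodendrocyte and 0 in venous cells. At most 10% mitochondrial UMIs gave 0 in arterial, 0 in astrocyte and 1 in smooth muscle cells; at least 1000 genes gave 0 in arterial cells, as did resolution 2.0. No doublet removal gave 0 in arterial, 0 in oligodendrocyte and 2 in venous cells, and 3 times the doublet share gave 0 in arterial, 2 in astrocyte and 2 in venous cells. At least 10 cells per library adds border macrophage-like cells, with 0 of 2601 genes called and 84 at an unadjusted p under 0.05.

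With 1 library left out, called genes ranged from 0 to 4 in arterial, 0 to 5 in astrocyte, 0 to 9 in capillary, 0 to 1 in all-zone, 0 to 2 in microglia, 0 to 6 in oligodendrocyte, 0 to 4 in pericyte, 0 to 4 in smooth muscle and 0 to 21 in venous cells. Lists past the threshold ranged from 2 to 9 in arterial, 6 to 10 in astrocyte, 6 to 12 in capillary, 6 to 15 in all-zone, 3 to 8 in fibroblast, 6 to 13 in microglia, 3 to 7 in oligodendrocyte, 2 to 9 in pericyte, 5 to 8 in smooth muscle and 3 to 11 in venous cells. Estimated correlation and fry gave 0 lists in every class. Leaving out genes that free RNA could bring removes most tested genes (8747 of 10195 in capillary cells); then 1 list passed in arterial, 4 in astrocyte, 1 in capillary, 1 in all-zone, 0 in fibroblast, 3 in microglia, 4 in oligodendrocyte, 0 in pericyte, 3 in smooth muscle and 0 in venous cells. The block gave 5 lists in astrocyte, 17 in microglia and 9 in venous cells.

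Directions turned for few values. In capillary cells Timp2 had log2 fold changes of −0.012 with at most 10% mitochondrial UMIs, −0.13 with at least 1000 genes, −0.11 without doublet removal and −0.0078 with 3 times the doublet share, and H2afx 0.0587 at resolution 0.5. Cdkn1a in all zones was 0.0022 without vehicle replicate 2, and with 1 library left out ranged from −0.94 to 0.0022. Capillary lists turned for immediate early (adjusted p = 0.939) and NF-kB genes (0.845) under the block, glucocorticoid (0.871) and p53 genes (0.759) without vehicle replicate 2, NF-kB genes without vehicle replicate 1 (0.78) or paclitaxel replicate 4 (0.918), and tight junctions without free-RNA genes (0.957). With 1 library left out the adjusted p ranged from 2.8e-06 to 0.871 for glucocorticoid, 0.187 to 0.759 for p53 and 0.0345 to 0.918 for NF-kB genes. High-score shares (paclitaxel minus vehicle, percentage points) turned in microglia at the 99th percentile (0.0392), at 2000 UMIs (0.328) and with the core list (0.273), in oligodendrocytes at 2000 UMIs (0.288) and in astrocytes with the core list (3.46). With the long secretory list they turned in capillary (0.379) and all-zone cells (1.18, exact p = 0.0357, adjusted p = 0.179). The difference in capillary high-score share ranged from −3.76 to −0.354 with 1 library left out, and that in mean score from −0.0169 to 0.00288. Mean scores turned in venous cells with the long list (0.0014) and in astrocytes with the core list (0.00899). Resolution 0.5 left no arterial class, no doublet removal no astrocyte class and 3 times the doublet share no fibroblast class to test. Cdkn2a had a UMI in 12 of 3776 capillary cells without thinning and in 1 of 3651 at equal depth. In simulated capillary counts with 200 changed genes 37.3% of genes changed 1.5-fold were recovered, without telling depth from the spread or number of libraries.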

Other observations

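The values here were picked out after the results were seen, and no further test was run on them.

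Tuba1b, an alpha-tubulin gene, had a negative log2 fold change in 9 of 9 separate classes, from −0.77 in arterial endothelial-like to −0.11 in oligodendrocyte-like cells. It passed the threshold in arterial cells. The 9 classes come from the same 8 libraries, so their shared direction is not replication. Capillary cells had 306 ± 18.4 CPM in vehicle and 232 ± 50.1 CPM in paclitaxel libraries, and pericyte-like cells 240 ± 30.6 and 183 ± 33.2 CPM. Its near-identical paralogs make these counts uncertain.

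The Xist and Y-linked gene levels differ from the sex given in the labels. Xist had a UMI in 85.5% to 88.6% of the kept cells of a library, and Uty in at most 0.133%.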
